A study of Homo sapiens with 6 samples.

How the data were processed

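6 RNA samples from HL-60 cells were profiled. HL-60 is an established acute myeloid leukemia line with a RAS mutation, and its cells resemble promyelocytes. Per the labels' protocols, the cells were transduced with a lentiviral vector carrying either a short hairpin RNA (shRNA) against EZH2 or a scrambled control hairpin, stable cells were selected with puromycin, and the drug was washed out 2 days before the experiment. The cultures were kept for 24 hours in RPMI medium with 0.05% fetal bovine serum before RNA was extracted. Libraries were made from polyadenylated RNA with a stranded kit and sequenced as single reads of 50 bases. The design text speaks of knock-out lines, whereas the sample labels describe a stable knockdown, and the second wording is used here.

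The authors deposited 2 tables with 1 column per library. The first holds raw counts, whole numbers of reads per gene that the authors deposited without normalization. The submitters' processing notes name STAR 2.5.2b, Picard 2.18.24, R 3.6.1, DESeq2 1.24.0 and the genome build GRCh38 (hg38). They give no role or order for these tools, and the program that counted reads, its annotation release and its strand setting are not given in the sources used here. Reads from genes that overlap on opposite strands may therefore not be separated in the counts. The deposited table also gives gene symbols and coordinates, which are used here as they stand, on GRCh38. Of its 58884 gene IDs, 58472 were found in the reference gene names. The second table holds FPKM values deposited by the authors. Dividing the counts by these FPKM values and by DESeq2 size factors returned a whole-number gene length, within a tolerance of 0.001, for 29060 of 29060 genes with a value above 0, so the FPKM table is a rescaled form of the same counts and not an independent measurement.

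Groups were taken from the labels: 3 control shRNA libraries, numbered 3, 4 and 5 in their titles, and 3 EZH2 shRNA libraries, numbered 1, 3 and 4. Total counts lay between 39717343 in control library 3 and 85074624 in EZH2 library 4. A floor of 3 counts, the upper limit that a count of 0 allows, corresponded to between 0.0353 and 0.0755 CPM per library. Counting intervals and floors cover counting error only, and reads without molecular identifiers are not independent molecules. Every pair of libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom between 3.18 and 17.6, so all 6 were used as separate samples. Nothing in the sources says whether the libraries of a group came from separate transductions or cultures, so p-values measure only the spread between these samples, which may be technical. The numbers in the titles are not said to pair the libraries.

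Computed here from the counts were CPM (counts scaled to library size with TMM factors), fold changes and tests. Of 58884 genes in the table, 29060 had a count in any library and 16859 passed filterByExpr with its default settings. Genes called measured are those that passed this expression filter. The test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with robust dispersion estimates, group as the only term, and Benjamini-Hochberg adjustment over the 16859 genes, at a threshold of 0.05. Log2 fold changes are EZH2 shRNA over control, and their standard errors (SE) were derived from the fold change and the F statistic. CPM values are means ± SD over 3 libraries.

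Before the data were examined, the test, 30 gene lists, the alternatives and the rule for naming genes were fixed. Named were EZH2 and EZH1, then the 12 genes higher and the 12 genes lower with the largest log2 fold change among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM over the 6 libraries and every EZH2 library on one side of every control library. Up to 4 members with the smallest p were named per list, and any measured member of the lists of ERK pathway target genes and PRC2 subunits. Pseudogenes and copies that share reads were to be named only with that limit. Some genes that this rule names are not reported here. Lists with at least 5 kept genes, 29 of the 30, were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, camera on ranks, and fry, which tests whether a list's genes move on balance one way without comparing them with other genes. Counts of members past the threshold are over all genes tested, with the count adjusted over the list alone beside them. Medians per chromosome used genes with a mean log2 CPM over 2, and windows held about 40 such neighbouring genes. Intervals of list and chromosome medians are 95% intervals from resampling the genes of the set as if they were independent. They do not measure the spread between samples.

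The scripts were tested on simulated counts with 200 changed genes, drawn from the mean of each gene over the EZH2 shRNA and control libraries, its dispersion and the library sizes. Of 50 genes changed at each size, edgeR recovered 28% at 1.2-fold, 74% at 1.5-fold, 82% at 2-fold and 96% at 4-fold among 16631 genes fitted, and 11 unchanged genes were called, 7.28% of the calls. A gene list shifted on its own was called and 0 of the 28 other lists were. Genes were drawn independently of each other, so this does not show how often lists of correlated genes are called. A shift given to chromosome 2 was recovered as a median of -0.29, with 506 genes of that chromosome called before the chromosome medians were removed and 0 after.

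Alternatives were DESeq2 size factors, plain library size or upper-quartile scaling, no expression filter or a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with a mean FPKM filter of 0.5 and without it, a block for the title number, each library left out in turn, and a threshold of 0.01. Only the title numbers 3 and 4 stand in both groups, so under the block the group difference comes from those libraries alone. A further alternative was an adjustment for GC content (GENCODE release 44 transcripts) and gene length, which 99.5% of kept genes had. Added after seeing the data were a p adjustment over the genes left without chromosomes 2, 11 and 13, taken from the same fit, and fits with the median of each chromosome or window removed from the EZH2 libraries. Lists of eosinophil genes, mast cell and basophil genes, neutrophil primary granule core genes, interferon signalling and regulator genes, and zinc finger genes were also drawn up after results had been seen, and their results stand apart under the other observations. Figures were drawn with matplotlib 3.10.9.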

Results

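HL-60 cells with a stable shRNA against EZH2 (3 libraries, numbered 1, 3 and 4) were compared with cells carrying a scrambled control shRNA (3 libraries, numbered 3, 4 and 5) by sequencing polyadenylated RNA after 24 hours in 0.05% serum. Total counts were 39717343, 51622861 and 42103176 in control libraries 3, 4 and 5, and 50809853, 53199783 and 85074624 in EZH2 libraries 1, 3 and 4. The comparison asks how gene expression in a RAS-mutated leukemia line differs when EZH2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex PRC2, is reduced. Of particular interest is the output of RAS and ERK signalling.

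EZH2 mRNA fell to 53.5% of its control level, and many genes moved with it in both directions. Interferon-stimulated genes fell as a group, with 35 of 37 measured members lower. Genes of DNA replication and mitosis, of cholesterol synthesis and of MHC class I presentation were also mostly lower, by smaller amounts, though these 3 lists did not pass with an estimated correlation (adjusted p = 0.267 with an estimated correlation for each). Single genes with very low control levels rose most, among them the eosinophil genes IL5RA and CLC. Of 25 measured ERK pathway target genes 12 rose and 5 fell, and as a group they did not pass the test.

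EZH2 (ENSG00000106462; GRCh38 chromosome 7, 148807383 to 148884321, minus strand) was at 149.5 ± 1.61 CPM in the control libraries and 79.98 ± 3.01 CPM in the EZH2 shRNA libraries (SD, n = 3 each). Its log2 fold change was -0.90 (SE 0.04, edgeR adjusted p = 3.22e-11). The highest EZH2 shRNA library had 83.21 CPM and the lowest control library 147.6 CPM. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. EZH1, the paralog that can replace EZH2 in PRC2, rose from 44.35 to 53.25 CPM (log2 fold change 0.26, edgeR adjusted p = 0.00047). EZH1 lies on chromosome 17, whose genes were slightly higher as a whole, and with the median of each chromosome removed the gene EZH1 was at 0.12 (edgeR adjusted p = 0.0778).

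**Figure D1:**
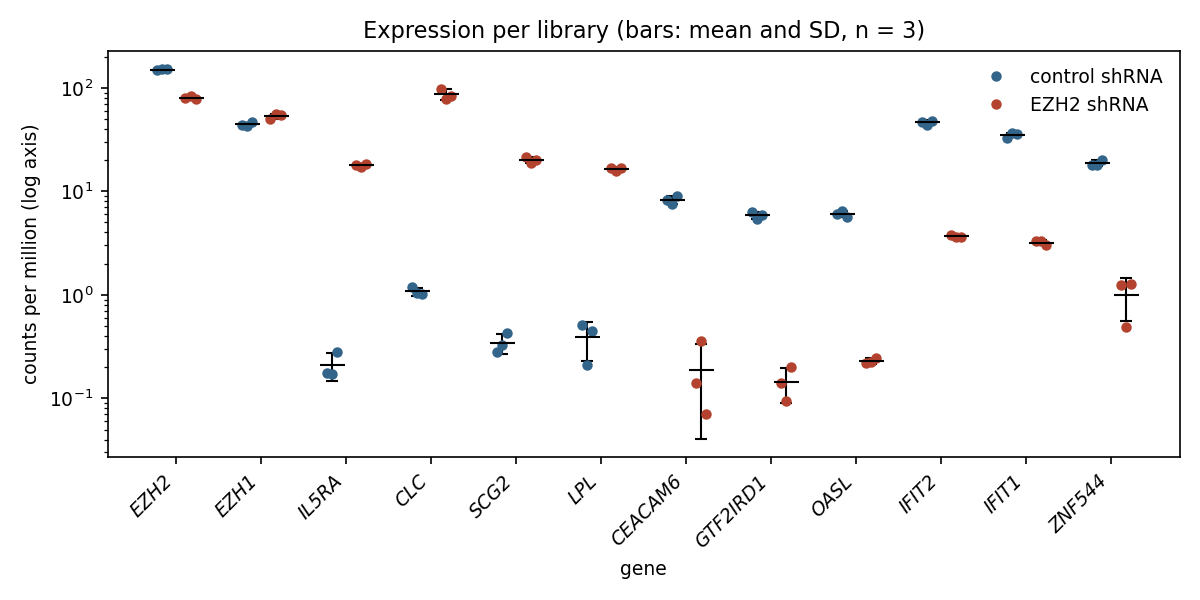
Expression in CPM (log axis) of 12 genes in each library, with control shRNA and EZH2 shRNA points side by side and bars at the mean ± SD (n = 3 each). EZH2 lies between 77.25 and 83.21 CPM in the EZH2 shRNA libraries and between 147.6 and 150.5 CPM in the control libraries.

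In all, 7866 of 16859 genes changed (46.7%), 4010 higher and 3856 lower, so 51% of changed genes were higher (exact binomial 95% interval 49.9 to 52.1). Most changes were small, with a median size of 0.38 on the log2 scale. At least 2-fold changes were found for 1102 genes, of which 735 were higher and 367 lower (66.7% higher, 63.8 to 69.5). The count of at least 2-fold changes was 615 with a filter of 1 CPM in 3 libraries, and 128, 378 and 127 in the FPKM fits (log2 of FPKM + 1, of FPKM + 0.1, and of unfiltered FPKM + 1). Rises outnumbered falls among weakly expressed genes. In the lowest of 3 equal parts by expression 984 genes rose and 518 fell (65.5% higher), against 1441 and 1478 in the middle part and 1585 and 1860 in the highest. The groups did not overlap for 54.9% of genes, where chance gives 10%. The first principal component held 70.1% of the variance and separated the groups. The p-values measure only the spread between these libraries, which may be technical, since separate transductions are not described.

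**Figure D2:**
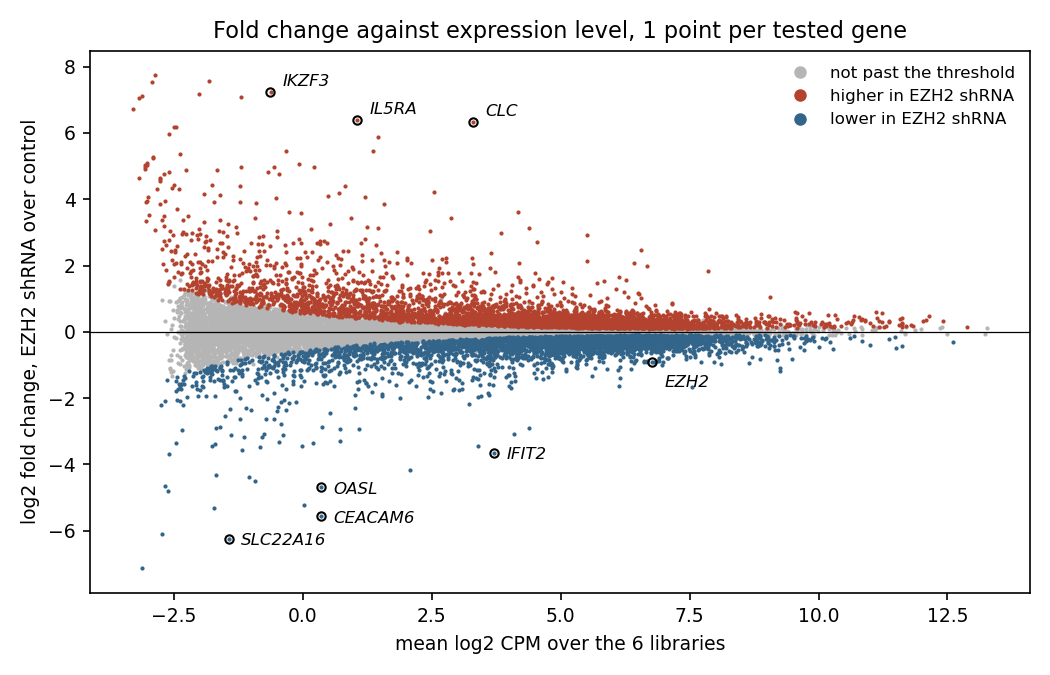
Log2 fold change of EZH2 shRNA over control (vertical axis) against mean log2 CPM (horizontal axis), 1 point per kept gene, with genes past the edgeR threshold coloured. The 4010 higher and 3856 lower genes lie at all levels, and the widest changes lie at the low end.

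Among the 12 genes with the largest rises, IKZF3, a lymphoid zinc finger transcription factor, went from 0.04 to 5.90 CPM (log2 fold change 7.22, SE 0.27, edgeR adjusted p = 2.72e-12). IL5RA, the interleukin 5 receptor chain of eosinophils, rose from 0.21 to 17.8 CPM, and CLC, the eosinophil crystal protein, from 1.08 to 86.5 CPM (log2 fold changes 6.39 and 6.33). SCG2, a secretory granule protein, and LPL, lipoprotein lipase, rose by 5.87 and 5.46. The GABA receptor gene GABBR1 was higher by 5.45 and the forkhead factor FOXN4 by 5.06. LHFPL6, SELP (P-selectin), TEX15 and GRIP1 were higher by 4.99, 4.98, 4.97 and 4.83. SLC1A1, a glutamate transporter, had 3 counts over the control libraries and 617 over the EZH2 shRNA libraries, a ratio of 145 with a counting interval of 49.4 to 706. SLC1A1 overlaps SPATA6L and GRIP1 overlaps HELB on the other strand, so part of their reads may belong to those genes.

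Among the 12 genes with the largest falls, SLC22A16, a carnitine transporter, went from 2.21 to 0.03 CPM (log2 fold change -6.25, SE 0.48, edgeR adjusted p = 4.66e-08). CEACAM6, a granulocyte adhesion molecule with close family copies, changed by -5.57 and GTF2IRD1, a transcription factor, by -5.24. Interferon-stimulated members of this group were OASL at -4.69, IFIT2 at -3.66 (46.4 to 3.69 CPM) and IFIT1 at -3.46 (34.9 to 3.19 CPM). The zinc finger genes ZFP28, ZNF544 and ZNF772 of chromosome 19 were lower by log2 fold changes of -4.39, -4.18 and -3.35. PXMP4, a peroxisomal membrane protein, was at -4.50, the long non-coding RNA AL133325.3 at -3.45 and ART3 at -3.31. Overlaps on the other strand leave CEACAM6 (AC243967.2), ZNF544 (AC020915.3), IFIT1 and IFIT2 (LIPA) and ART3 (CXCL10, CXCL11) less certain.

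Of the ERK pathway target genes, 12 of 25 rose, 5 fell and 8 did not pass, and the same counts held adjusted over the list alone (camera adjusted p = 0.0805). The immediate early genes EGR3, EGR1, EGR2 and FOS rose by 2.10, 0.32, 1.10 and 0.61 on the log2 scale, as did IER3 (1.78), CXCL8 (0.48), PLAUR (0.64) and the feedback gene SPRY4 (1.85). SPRY2 at 0.22 and DUSP5 at 0.36 were higher by less. DUSP4, a phosphatase that acts on ERK, and the ETS factors ETV1, ETV5 and ETV4 changed by -1.36, -0.85, -0.38 and -0.26. SPRED2, on chromosome 2, was at -0.34. DUSP6 at 0.11 (edgeR adjusted p = 0.0426) and PHLDA1 at 0.28 (0.0493) passed narrowly. The genes without a call included CCND1 (-0.19), FOSL1 (0.02), SPRED1 (-0.06) and SPRY1 (0.06), with MAFF at 0.21, KCNN4 at 0.57, IER2 at 0.15 and SPRED3 at 0.14. Leaving out single libraries ended the calls of the gene DUSP6 (adjusted p 0.139 without control 3, 0.196 without control 5, and 0.0897, 0.131 and 0.0654 without EZH2 libraries 1, 3 and 4). The gene PHLDA1 likewise lost its call (0.236 and 0.0759 without controls 3 and 5, and 0.109, 0.1 and 0.0677 without EZH2 libraries 1, 3 and 4). Counting all alternatives, 14 ended the call of DUSP6 and 16 that of PHLDA1, among them DESeq2 size factors (0.0554 and 0.0535), library size only (0.0783 and 0.0675), DESeq2 (0.0842 and 0.0795), log2 of FPKM + 1 (0.0795 and 0.149) and the title-number block (0.195 and 0.0811). Without control 4 the list passed (0.0412) and so did the gene IER2 (0.00188), and without EZH2 library 3 the gene MAFF passed (0.0454). With the chromosome medians removed the gene SPRED2 was at -0.04 (adjusted p = 0.587), the gene SPRY2 at 0.01 (0.858) and the gene FOSL1 at 0.29 (0.00402).

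**Figure D3:**
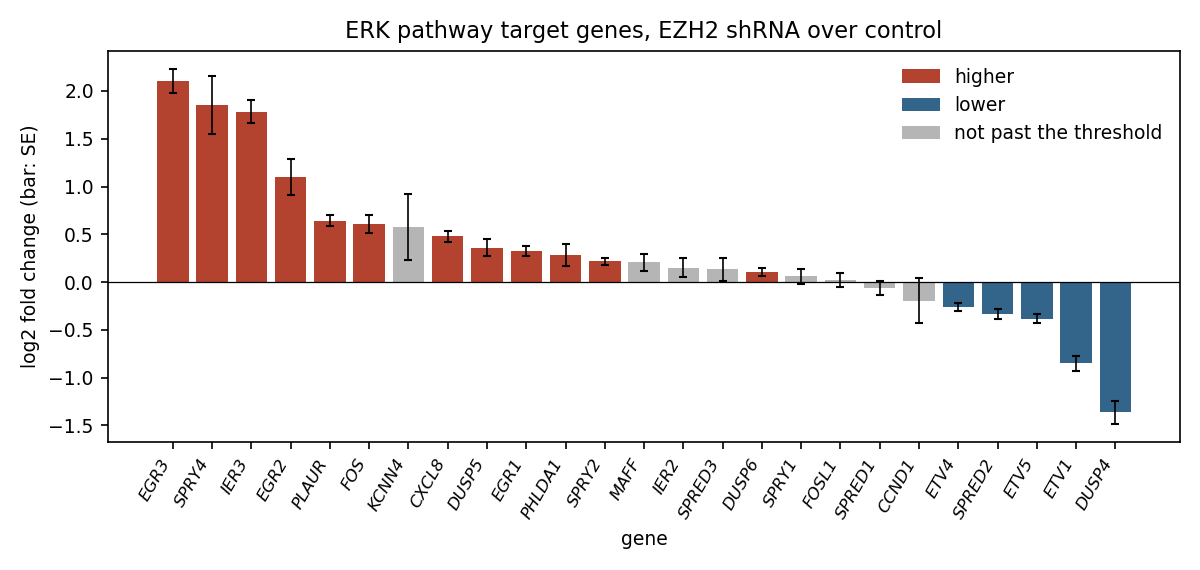
Log2 fold change of EZH2 shRNA over control (axis) with its SE for the 25 measured ERK pathway target genes, 1 bar per gene. EGR3 (2.10), SPRY4 (1.85) and IER3 (1.78) stand highest and DUSP4 (-1.36) lowest.

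Of the RAS pathway components, 6 of 34 rose, 16 fell and 12 did not pass (7 and 16 adjusted over the list alone; camera adjusted p = 0.0656). GAB2, an adaptor protein, fell (-0.98), as did RPS6KA1, a kinase below ERK (-0.73), whereas RASGRP2, an exchange factor for small GTPases, rose by 0.49. GAB2 and RASGRP2 lie on chromosome 11. Without EZH2 library 3 the list passed (camera adjusted p = 0.0448). Among AP-1 family genes 5 of 13 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 0.301), with FOSL2 at -0.79, MAFG at 0.40 and FOSB at 0.76. The NF-kB and inflammatory cytokine genes held 14 rises and 6 falls among 25 (14 and 7 adjusted over the list alone; camera adjusted p = 0.0805). TNF rose by 1.42 and TNFAIP2 by 0.93, while TNFAIP3, an inhibitor of NF-kB, was at -0.71.

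Interferon-stimulated genes were lower in 35 of 37 cases and higher in 0, the same adjusted over the list alone (median -1.43, camera adjusted p = 1.54e-21). This was the only list past the threshold with an estimated correlation as well (adjusted p = 0.0181 with an estimated correlation). On log2 of FPKM + 1, which shrinks changes of weakly expressed genes, the median was -0.89 with the filter and -0.59 without it. IFIT3 fell by 3.08 and the double-stranded RNA sensor kinase EIF2AK2 by 1.12 on the log2 scale. IFIT3 overlaps LIPA on the other strand. Of the 37 members 10 lie on chromosomes 2 and 11, all 10 of them lower, and without chromosomes 2, 11 and 13 there were 25 of 27 lower with a median of -1.49. MHC class I presentation genes were lower in 15 of 20 cases and higher in 1, the same adjusted over the list alone (median -0.32, camera adjusted p = 4.17e-05; adjusted p = 0.267 with an estimated correlation). ERAP2, a peptide-trimming enzyme, was at -1.09, the immunoproteasome genes PSMB9 and PSMB8 at -1.03 and -0.50, and HLA-E at -0.39. PSMB8 and PSMB9 overlap each other on opposite strands. Only 3 of 18 MHC class II presentation genes passed the expression filter, too few for a list test. CIITA, their main activator, rose by 2.14 from 0.12 CPM and HLA-DMA by 1.49, and the protease gene CTSS fell by 0.38, also adjusted over the list alone.

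**Figure D4:**
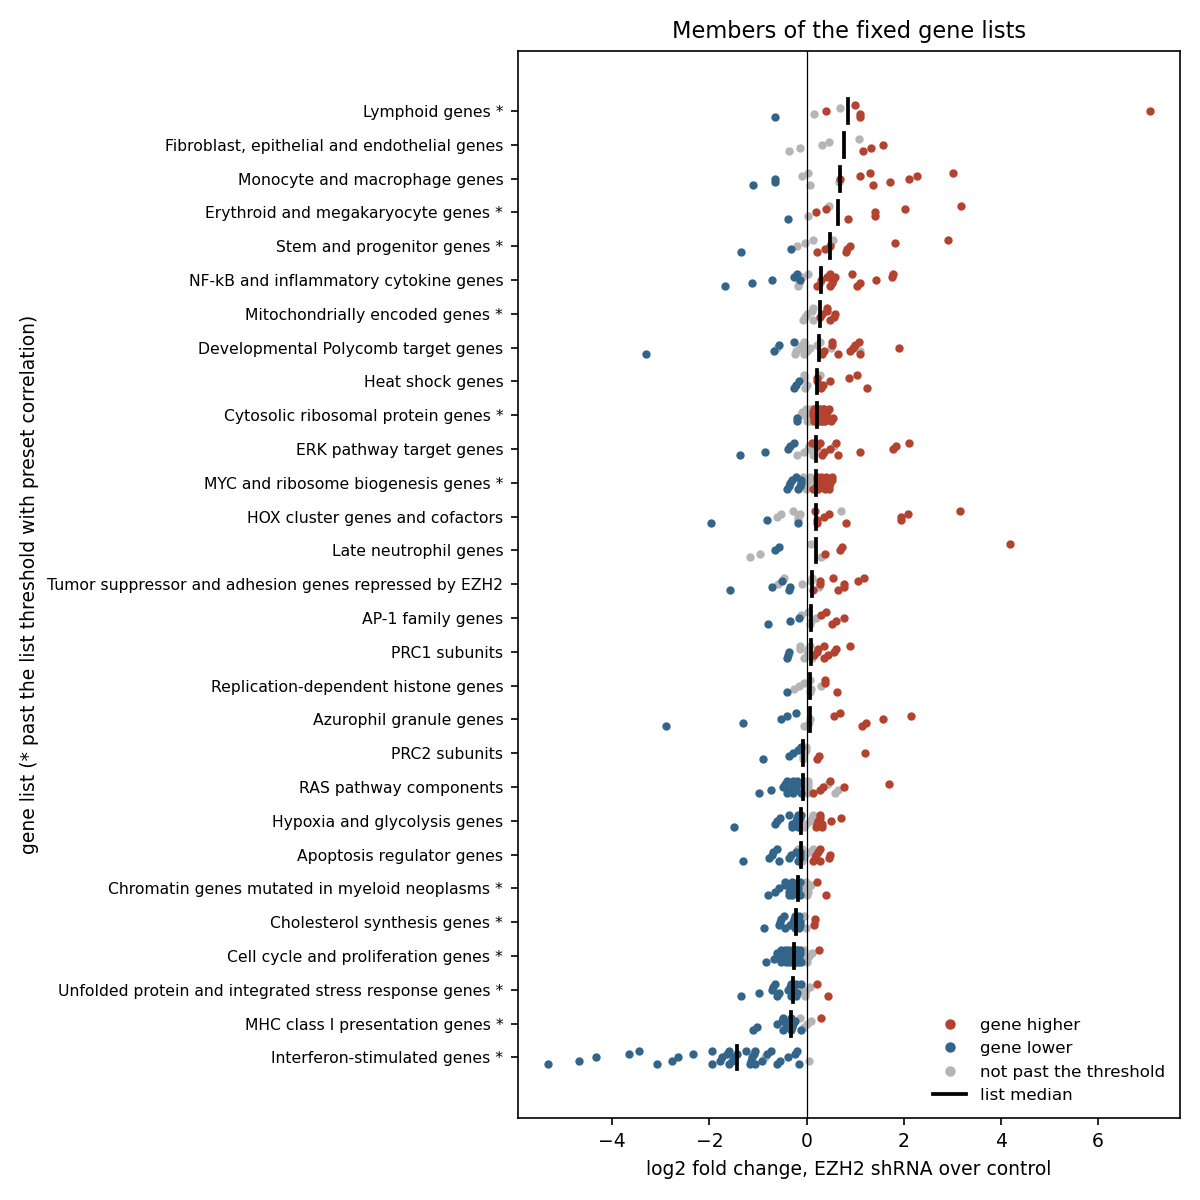
Log2 fold change (horizontal axis) of every measured member of each gene list, 1 point per gene, with a black bar at the list median and a star where the list passed the camera threshold. The interferon-stimulated genes lie furthest to the left, with a median of -1.43.

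Cell cycle and proliferation genes fell in 40 of 50 cases and 1 rose (42 and 2 adjusted over the list alone; median -0.25, camera adjusted p = 1.74e-11; adjusted p = 0.267 with an estimated correlation). The ribonucleotide reductase genes RRM2 and RRM1 were at -0.82 and -0.61, the replication helicase gene MCM6 at -0.61 and the mitotic kinase gene BUB1 at -0.53. These 4 lie on chromosomes 2 and 11, which hold 6 members of the list. Without chromosomes 2, 11 and 13, 34 of 44 members were lower. MYC and ribosome biogenesis genes rose in 19 of 35 cases and fell in 9, the same adjusted over the list alone (median 0.20, camera adjusted p = 0.0204; adjusted p = 0.397 with an estimated correlation). The median was 0.13 without EZH2 library 1 and 0.12 with the title-number block. MYC rose from 976 to 1398 CPM (0.52), and NOP56 and GNL3 by 0.49 and 0.46, whereas DDX18, on chromosome 2, was at -0.41. All 9 that fell lie on chromosomes 2 and 11. With window medians removed the gene DDX18 was at -0.10 (adjusted p = 0.0513) and the gene MAFG, named above, at 0.10 (0.0598). Cytosolic ribosomal protein genes rose in 39 of 57 cases and fell in 2 (41 and 2 adjusted over the list alone; median 0.21, camera adjusted p = 2.27e-07; adjusted p = 0.397 with an estimated correlation). RPL38, RPL23 and RPL26 of chromosome 17 rose by 0.55, 0.51 and 0.42 and RPL28 by 0.39. Reads of these genes can also match their pseudogene copies. Mitochondrially encoded genes rose in 7 of 13 cases with 0 lower, the same adjusted over the list alone (camera adjusted p = 0.00327; adjusted p = 0.292 with an estimated correlation). Unfiltered FPKM ended that call (0.0542). MT-CYB was at 0.56, MT-CO3 at 0.48 and MT-ATP6 at 0.42, and nuclear copies may share their reads. Mitochondrial counts made up between 3.62% and 4.01% of the EZH2 shRNA libraries and between 3.23% and 3.28% of the controls. Replication-dependent histone genes, few of which carry poly(A) tails, rose in 3 of 11 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.513). HIST1H2BD was at 0.63 and the gene HIST1H2BK at 0.39, a call that ended with the GC content and gene length adjustment (adjusted p = 0.0804). The gene HIST1H2AC at 0.37 lost its call without control 4 (0.0593), control 5 (0.0985) or EZH2 library 4 (0.0877). The gene HIST2H4A at -0.40, which has an identical copy, lost it without control 5 (0.247), EZH2 library 3 (0.0539) or EZH2 library 4 (0.0927). Counting all alternatives, 5 ended the call of HIST1H2AC and 8 that of HIST2H4A, among them DESeq2 (0.0536 and 0.0501) and the title-number block (0.126 and 0.237).

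Cholesterol synthesis genes fell in 18 of 24 cases and rose in 2 (19 and 2 adjusted over the list alone; median -0.21, camera adjusted p = 2.8e-05; adjusted p = 0.267 with an estimated correlation). TM7SF2 and DHCR7, reductases of the sterol pathway on chromosome 11, were at -0.87 and -0.53, ACAT2 at -0.54 and the sterol carrier gene STARD4 at -0.56. The unfolded protein and integrated stress response genes fell in 18 of 26 cases and rose in 2, the same adjusted over the list alone (median -0.28, camera adjusted p = 2.92e-05; adjusted p = 0.267 with an estimated correlation). The folate enzyme gene MTHFD2 was at -0.98, the cystine transporter gene SLC7A11 at -1.36, the serine synthesis gene PSAT1 at -0.71 and the lipoprotein receptor gene VLDLR at -0.57. Heat shock genes rose in 8 of 16 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.0656, and 0.0295 without EZH2 library 3). HSPH1 was at 0.88, HSPA1B, which shares reads with its copy HSPA1A, at 1.23, DNAJA1 at 0.48 and AHSA1 at 0.34. Hypoxia and glycolysis genes went both ways, 9 higher and 14 lower of 29 (10 and 15 adjusted over the list alone; camera adjusted p = 0.329), with PDK1 at -0.61, ENO2 at -0.66, BNIP3L at -0.55 and SLC2A3 at 0.51. Of the 14 that were lower, 5 lie on chromosomes 2 and 11, and without chromosomes 2, 11 and 13 there were 9 higher and 9 lower (median 0.03, against -0.11 with all chromosomes). Apoptosis regulator genes were higher in 8 and lower in 13 of 28 cases, the same adjusted over the list alone (camera adjusted p = 0.102). The death effectors APAF1 and CASP8 were at -0.71 and -0.57 and PMAIP1 at -0.70. With window medians removed 9 were higher and 9 lower.

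Among PRC2 subunits 3 of 13 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.31), and 3 rose and 3 fell with upper-quartile scaling. EPOP, a PRC2 cofactor, rose by 1.21 and JARID2 by 0.22, while PHF19 was at -0.29 and EED, on chromosome 11, at -0.37. The gene EED was at -0.10 with chromosome medians removed (adjusted p = 0.215). SUZ12 (-0.02), RBBP4 (-0.06), PHF1 (-0.06), LCOR (-0.06) and MTF2 (-0.01) did not pass, and with chromosome medians removed the gene SUZ12 did (-0.17, adjusted p = 0.004). The gene RBBP7 at -0.12 lost its call without control 3 (0.0703), control 4 (0.0809), control 5 (0.061) or EZH2 library 4 (0.109). The gene AEBP2 at -0.17 lost it without control 4 (0.215), control 5 (0.0607) or EZH2 library 4 (0.145). Counting all alternatives, 7 ended the call of RBBP7 and 10 that of AEBP2, among them upper-quartile scaling (0.06 and 0.0645), unfiltered FPKM (0.0861 and 0.171) and the GC content and gene length adjustment (0.298 and 0.343). PRC1 subunits rose in 9 of 20 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.0981), with PHC1 at 0.89, PCGF2 at 0.60, PCGF5 at 0.57 and CBX8 at 0.44. Chromosomes 13 and 17, whose genes were higher as a whole, carried 3 of these 9 rises and 2 of the 3 PRC2 rises. Chromosomes 2 and 11, lower as a whole, carried 1 fall in each of these 2 lists. HOX cluster genes and cofactors rose in 10 of 20 cases and fell in 3 (10 and 5 adjusted over the list alone; camera adjusted p = 0.213). HOXB9 rose by 3.15 from 0.77 CPM, HOXC8 by 2.08, HOXC4 by 1.95 and the gene HOXB6 by 1.94, a call that ended with unfiltered FPKM (adjusted p = 0.0533). Of 100 developmental Polycomb target genes, all in the count table, 50 had a count in any library and 28 passed the expression filter. Of these 28, 11 rose and 4 fell, or 12 and 4 adjusted over the list alone. The camera adjusted p was 0.105, and 0.0464 without control 4. Chromosomes 13 and 17 carried 4 of the 11 rises, and chromosomes 2 and 11 carried 3 of the 4 falls. Among HOX cluster genes and cofactors these numbers were 2 rises and 2 falls. POU4F1 and PAX5 rose by 1.08 and 1.09 and GATA6 by 1.91, whereas PAX6, on chromosome 11, fell by 3.30. Tumor suppressor and adhesion genes repressed by EZH2 held 9 rises and 5 falls among 20 (10 and 5 adjusted over the list alone; median 0.12, from 0.05 with the GC content and gene length adjustment and 0.06 with unfiltered FPKM to 0.20 without a filter and 0.19 without control 4; camera adjusted p = 0.643). Camera placed this list up and fry, which tests whether members move on balance one way, placed it down (adjusted p = 0.99). RUNX3 and the cell cycle inhibitor CDKN2C were at -0.71 and -0.51. The gene BCL2L11, on chromosome 2, was at -0.37 and at -0.07 with chromosome medians removed (adjusted p = 0.267). Chromatin genes mutated in myeloid neoplasms fell in 20 of 31 cases and rose in 2, the same adjusted over the list alone (median -0.17, camera adjusted p = 0.000151; adjusted p = 0.267 with an estimated correlation). The median was -0.11 with the title-number block. IDH1 and ASXL2, both on chromosome 2, were at -0.66 and -0.58, SMC3 at -0.36 and NSD2 at -0.33.

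Genes of the myeloid stages of HL-60 moved both ways. Azurophil granule genes rose in 6 of 14 cases and fell in 5, the same adjusted over the list alone (camera adjusted p = 0.307). CLEC5A, a lectin receptor, went from 57.5 to 7.68 CPM (-2.90), while PRSS57, RNASE3 and RNASE2 rose by 1.57, 1.14 and 0.56. CLEC5A overlaps MGAM on the other strand. Late neutrophil genes rose in 4 of 10 cases and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.307), with TCN1 at 4.19, NCF4 at 0.68, CEBPE at 0.38 and ITGB2 at -0.57. Stem and progenitor genes rose in 8 of 15 cases and fell in 2, the same adjusted over the list alone (median 0.49, camera adjusted p = 0.026; adjusted p = 0.267 with an estimated correlation). The call ended with the CPM filter (0.0858) and with both filtered FPKM fits (0.0715 and 0.0684), with medians of 0.31, 0.21 and 0.29, and the median was 0.03 with unfiltered FPKM. The hematopoietic factor gene GATA2 rose from 122.5 to 435.4 CPM (1.83), MSI2 by 0.81 and RUNX1 by 0.39, and ID2, on chromosome 2, was at -1.35.

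Markers of other cell types were measured in small numbers. Monocyte and macrophage genes rose in 8 of 15 cases and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.0656, and 0.0444 and 0.0279 without controls 3 and 5). FCGR1A, which has near-identical copies, and FCGR2A, both Fc receptors, rose by 1.30 and 1.37 and TLR4 by 0.69, and CD4 was at -0.65. Erythroid and megakaryocyte genes rose in 7 of 10 cases and fell in 1, the same adjusted over the list alone (median 0.66, camera adjusted p = 0.0118; adjusted p = 0.267 with an estimated correlation). This call too ended with the CPM filter (0.0788) and the filtered FPKM fits (0.0699 and 0.0684), with medians of 0.32, 0.28 and 0.30, and the median was 0.03 with unfiltered FPKM. NFE2 rose by 1.41, KLF1 by 0.86, TFRC by 0.41 and GFI1B by 3.18 from 0.03 CPM. Lymphoid genes rose in 5 of 8 cases and fell in 1 (6 and 1 adjusted over the list alone; median 0.85, camera adjusted p = 0.00978; adjusted p = 0.267 with an estimated correlation). The filtered FPKM fits ended the call (0.0707 and 0.0684), with medians of 0.33 and 0.38, and the median was 0.02 with unfiltered FPKM. CD247 was at 1.09 and LEF1 at 0.39, and GATA3, with 0 control counts and 60 in the EZH2 shRNA libraries, was at least 14.1-fold higher against a floor of 3 counts over the group, taking the 60 counts as exact (lower counting limit 11.1). With GATA3 at this bound the list median stayed 0.85. Fibroblast, epithelial and endothelial genes rose in 3 of 8 cases with 0 lower, the same adjusted over the list alone (camera adjusted p = 0.0805, and 0.0499 without control 3). KRT8, which has pseudogene copies, rose by 1.32, MUC1 by 1.17 and ACTA2 by 1.57, and the gene PECAM1 at 1.07 did not pass (0.0585), though it did with limma-voom (0.0433), with the title-number block (0.033) and without control 5 (0.0263).

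Expression also differed by chromosome. Genes of chromosomes 2 and 11 were lower as a whole, with medians of -0.30 and -0.27 on the log2 scale, and those of chromosomes 13 and 17 higher, with medians of 0.20 and 0.15. Chromosome 2 held 542 lower and 98 higher genes and chromosome 11 held 424 and 96. All 18 windows of chromosome 2 and all 15 of chromosome 11 had a median below 0. Medians of the other chromosomes lay between -0.07 and 0.07, but some of their regions stood apart. The highest window of all, at 0.35, was on chromosome 7 from 149262171 to 158956747, next to EZH2, and the window from 128297685 to 135693418 was at 0.24. On chromosome 20 the windows from 270863 to 4701590 and from 4780023 to 20712644 were at 0.23 and 0.22. Chromosomes 2 and 11 carried 11.7% of measured genes and 25.1% of the lower ones. Without chromosomes 2, 11 and 13, 6490 genes passed, 3638 higher and 2852 lower, so that 56.1% were higher. Chromosome 17, also higher as a whole, stayed in this set, with 391 higher and 92 lower genes in the reported test.

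**Figure D5:**
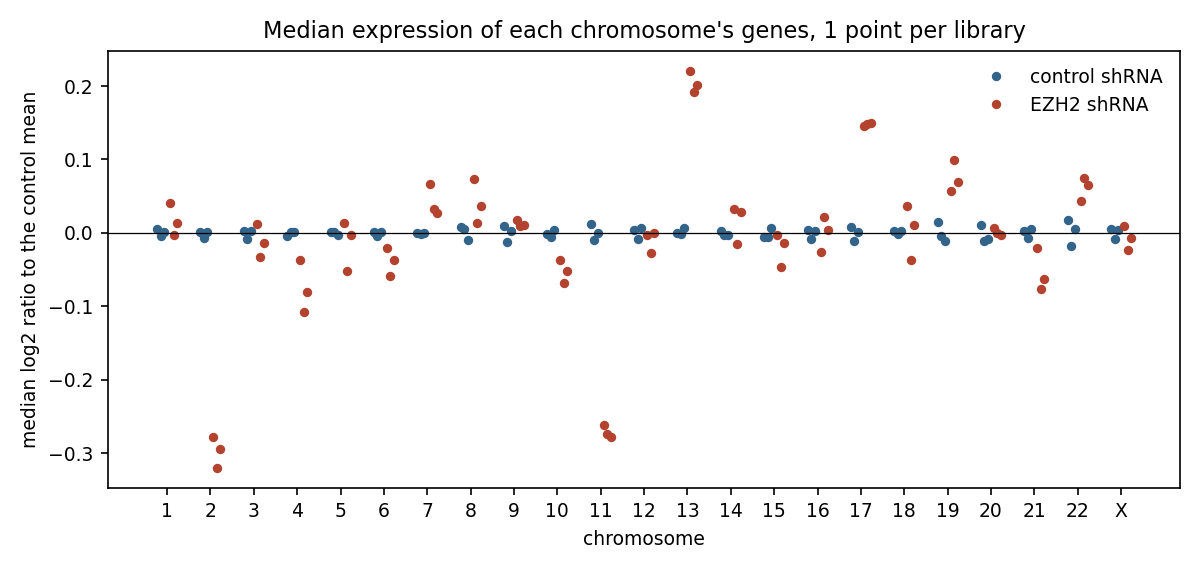
Median log2 CPM relative to the control mean (vertical axis) of the genes of each chromosome (horizontal axis), 1 point per library, control shRNA beside EZH2 shRNA. Chromosomes 2 and 11 lie low in all EZH2 shRNA libraries, with median log2 fold changes of -0.30 and -0.27, and chromosome 13 lies high at 0.20.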

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

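The tests without chromosomes 2, 11 and 13 and those with chromosome or window medians removed were chosen only after the result was seen. EZH2 stayed lower and past the threshold under every alternative, with log2 fold changes from -1.04 (window medians removed) to -0.83 (GC content and gene length adjusted). The count of changed genes ranged from 5906 (unfiltered FPKM) to 8124 (GC content and gene length adjusted), and was 6007 at an adjusted p of 0.01. No scaling moved the median of all genes past 0.03. Of the values for summaries and lists under all alternatives 721 stayed the same, 28 moved, 51 gained a call, 20 lost one and 4 turned direction. For lists and EZH2 the same means direction and call, whether called or not. For counts and shares it means within a fixed range of the reported value. Of the values for named genes 3313 kept their direction and call, 72 lost a call and 11 gained one. Another 17, none of them a call in the reported test, turned direction. The title-number block left 7721 changed genes, with the group difference taken only from the libraries numbered 3 and 4. Deviations of libraries with the same number correlated by 0.11 and 0.12. The other pairs of a control and an EZH2 library lay lower, between -0.14 and 0.053. A pairing is thus not excluded, though the same-number pairs are too few to show one. Small changes can be missed, and in the simulation 28% of 1.2-fold changes were recovered. Only 200 genes were changed there, against 7866 genes called in the data, which makes the adjusted threshold stricter in the simulation. The 28% is therefore not the share recovered in these data. Except where genes or libraries were removed by construction, the cause was not tested.

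The share of higher genes among changed genes (51%) was 49.8% with DESeq2 size factors, 48.5% with library size only, 54.8% with the upper quartile, 52.1% with no filter, 49.5% with DESeq2, 46.7% with either filtered FPKM fit, 48.3% with unfiltered FPKM, 56.1% without chromosomes 2, 11 and 13, 53.6% and 53.4% with chromosome or window medians removed, and 48.4% to 50.5% with 1 library left out. In the lowest of 3 parts by expression it was 72.2% with no filter, 60% with the CPM filter, 52.2%, 52.5% and 71.7% with FPKM + 1, FPKM + 0.1 and unfiltered FPKM, 62.4% with the GC adjustment and 68.3% with window medians removed. Genes changed at least 2-fold numbered 615 with the CPM filter and 128, 378 and 127 with those FPKM fits.

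Lists past the threshold numbered 19 with no filter, 20 with window medians removed, 1 with an estimated correlation and 27 with fry. The adjusted p without a filter was 0.0422 for PRC1 subunits, 0.0274 for ERK targets, RAS components and NF-kB genes, 0.0465 for fibroblast, 0.0215 for heat shock and 0.0474 for apoptosis genes, and late neutrophil genes turned direction (0.877). With the CPM filter it was 0.0401 for RAS components, 0.0858 for stem and 0.0788 for erythroid genes. With FPKM + 1 it was 0.0328 for RAS components, 0.0715 for stem, 0.0699 for erythroid and 0.0707 for lymphoid genes. With FPKM + 0.1 it was 0.0331 for RAS components and 0.0684 for the other 3. Unfiltered FPKM gave 0.0379 for ERK targets and RAS components, 0.0412 for NF-kB, 0.0476 for heat shock and 0.0542 for mitochondrial genes, and late neutrophil genes turned (0.909). The block gave 0.0365 for monocyte genes. The GC adjustment gave 0.0376 for heat shock genes and turned PRC2 subunits (0.988). Without chromosomes 2, 11 and 13 RAS components had 0.012 and heat shock genes 0.00989. With chromosome medians removed RAS components had 0.0225, developmental genes 0.0453 and heat shock genes 3e-04. With window medians removed ERK targets had 0.0399, RAS components 0.0445, HOX and monocyte genes 0.0497, developmental genes 0.0389, fibroblast 0.0464, NF-kB 0.0435 and heat shock genes 0.000382. An estimated correlation ended the calls of stem, erythroid, lymphoid, MHC class I, cell cycle, cholesterol, unfolded protein and chromatin genes (0.267), MYC and ribosomal protein genes (0.397) and mitochondrial genes (0.292). With fry the values were 0.00226 for PRC2, 0.000407 for PRC1, 0.0025 for ERK targets, 0.000833 for RAS components, 0.000965 for HOX, 0.00856 for developmental, 0.000411 for azurophil and apoptosis, 0.000615 for late neutrophil, 0.0059 for monocyte, 0.0127 for fibroblast, 0.000945 for NF-kB, 0.00353 for heat shock, 0.00772 for hypoxia and 0.0207 for histone genes, and tumor suppressor genes turned (0.99). With 1 library left out the ranges were 0.0412 (without control 4) to 0.117 for ERK targets, 0.0448 (EZH2 library 3) to 0.0964 for RAS components, 0.0464 (control 4) to 0.259 for developmental genes, 0.0279 (control 5) to 0.143 for monocyte genes, also called without control 3 (0.0444), 0.0499 (control 3) to 0.135 for fibroblast genes and 0.0295 (EZH2 library 3) to 0.124 for heat shock genes.

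Genes that turned direction had small log2 fold changes. The upper quartile put the gene SUZ12 at 0.002 and the gene MTF2 at 0.008, and the block the gene SPRED1 at 0.011. The GC adjustment gave the gene RBBP4 0.023, the gene LCOR 0.069, SUZ12 0.086, MTF2 0.095 (adjusted p = 0.0451, past the threshold), SPRED1 0.067 and the gene FOSL1 -0.056. The gene CCND1 was at 0.077 with chromosome medians and at 0.048 with window medians removed, where SPRED1 was at 0.01. With 1 library left out MTF2 ranged from -0.048 to 0.006 (without control 5), CCND1 from -0.393 to 0.036 (EZH2 library 4) and FOSL1 from -0.03 (EZH2 library 4) to 0.08.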

Other observations

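The tests of gene dosage and cell share as explanations for interferon-stimulated and eosinophil genes, and the lists of eosinophil, mast cell and basophil, neutrophil primary granule core, interferon signalling and regulator, and zinc finger genes were chosen only after the result was seen.

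Of 10 measured eosinophil genes 9 rose and 0 fell in the EZH2 shRNA libraries (median log2 fold change 2.07). The rises of CLC, EPX and IL5RA prompted this list, so its test is given without them, when 6 of 7 rose with a median of 1.14 (camera adjusted p = 0.000248; adjusted p = 0.105 with an estimated correlation). Of those 7, RNASE2, RNASE3, CEBPE and GATA1 also stand in fixed lists, which leaves PRG2, PRG3 and ADGRE1, too few for a list test. The granule protein genes EPX, PRG3 and PRG2 rose by 4.21, 2.44 and 2.10, GATA1 by 2.03, RNASE3 by 1.14, RNASE2 by 0.56 and CEBPE by 0.38. ADGRE1 at -0.13 did not pass. Mast cell and basophil genes rose in 7 of 11 cases and fell in 3 (median 2.15, also with CPA3 at its bound). HDC, IL1RL1, CSF2RB and SLC45A3 prompted this list, and without them 3 of 7 rose and 3 fell, with a median of 0.17 (camera adjusted p = 0.54). Its members GATA2, CTSG and MS4A3 also stand in fixed lists. IL1RL1, the interleukin 33 receptor, rose by 3.25, the histamine-forming enzyme HDC by 2.79, SLC45A3 by 2.70 and CSF2RB by 2.68, and IL3RA was at -1.34. CPA3 had 2 counts over the control libraries and 92 over the EZH2 shRNA libraries, a ratio of 32.5 with a counting interval of 8.74 to 272. Among neutrophil primary granule core genes PRTN3, PRSS57 and AZU1 rose by 2.14, 1.57 and 0.69 and CTSG was at -0.22.

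Interferon signalling and regulator genes fell in 11 of 18 cases and rose in 4. Several of these, IRF7, IRF9, STAT2, IFIH1 and DDX58 among them, are also in the list of interferon-stimulated genes, and IRF1 is in that of MHC class I presentation. Without members of fixed lists 4 of 11 rose and 4 fell (camera adjusted p = 0.942). IRF9 was at -1.95, IRF7 at -1.59 and IFIH1 at -1.52, while the adaptor gene MAVS was at 0.23. The falls of ZFP28, ZNF544 and ZNF772 prompted a look at zinc finger genes, picked by symbol only. Zinc finger genes with other symbols, such as IKZF3, were left out, so the set does not stand for the whole class. The protein-coding genes with ZNF, ZFP, ZKSCAN or ZSCAN symbols are given here without the 3 prompting genes. As a whole they held 58 rises and 120 falls among 385, and 207 did not pass (camera adjusted p = 0.0216; adjusted p = 0.103 with an estimated correlation). Those on chromosome 19 held 50 falls and 17 rises among 155, and 88 did not pass (camera adjusted p = 0.00515; adjusted p = 0.0403 with an estimated correlation), whereas other protein-coding genes on chromosome 19 held 274 rises and 100 falls among 685, and 311 did not pass (camera adjusted p = 0.000695; adjusted p = 0.172 with an estimated correlation). The odds ratio of lower against higher calls between these was 8.01 (4.31 to 15.6, Fisher's exact test p = 1.88e-13, across genes that are not independent).

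The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05, and 1 of them, the real one, gave the most genes and lists. It gave 7866 changed genes, 1102 changed at least 2-fold and 12 lists. With edgeR the highest of the other splits gave 0, 0 and 10, with at most 266 genes at an unadjusted p under 0.05. With DESeq2 the highest of the others gave 1 gene and with limma-voom 0. Every one of the other splits gave between 5 and 10 lists with camera at its preset correlation. List calls at the preset correlation thus also arose between libraries of mixed groups. Camera with an estimated correlation was not run on these splits. Each of these splits, however, sets most control libraries against most EZH2 libraries and keeps part of the group difference. The rest of that difference adds to the spread, which makes gene calls unlikely. These splits therefore cannot show how many genes or lists would pass without a group difference.

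Like that of chromosome 17, the shift of chromosomes 2, 11 and 13 was present in all EZH2 shRNA libraries. Bias by GC content and gene length is argued against as its whole cause, since the median of chromosome 2 stayed at -0.26 (interval -0.284 to -0.24) after the adjustment. A difference in gene dosage of whole chromosomes between the control and EZH2 shRNA cells remains a possible explanation. The median of chromosome 2 was -0.25 or lower in each of 3 parts of its genes by expression level. That of chromosome 11 was -0.20 (interval -0.26 to -0.16) in the lowest part and -0.32 (-0.347 to -0.285) in the highest. Its shift was thus not equal at all levels. That of chromosome 13 lay between 0.18 and 0.22 in the 3 parts. Whether EZH2, the vector or a clone would underlie such a difference was not tested, as each arm is described with a single kind of shRNA and DNA was not measured.

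The fall of interferon-stimulated genes (median -1.43, interval -1.73 to -1.06) was larger than the shift of any region, since medians of windows of about 40 neighbouring genes were at most 0.41 in size. This argues against gene dosage of chromosome regions of that size as its whole cause, and smaller regions were not tested. A lower interferon response with less EZH2, and a difference between the control and EZH2 vectors or cell pools in how they trigger that response, both stay open and untested.

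The rise of eosinophil genes without CLC, EPX and IL5RA had a median of 1.14. Its interval (0.379 to 2.1) reaches below the largest window median, 0.41 in size, so the size of the median does not settle gene dosage for these 7 genes. With window medians removed, 9 of all 10 measured eosinophil genes, CLC, EPX and IL5RA included, were still higher. Of the 10, 7 were still at least 2-fold higher. The medians of windows thus did not account for the whole rise of the 9 genes still higher. CLC, EPX and IL5RA were picked for their rises in these data, so these counts do not settle gene dosage for the list. A part played by gene dosage stays open, and smaller regions were not tested. A larger share of eosinophil-type cells in place of promyelocyte-type cells cannot be told apart from a change within all cells. The neutrophil primary granule core genes had a median of 0.69 (interval -0.223 to 2.14), and the most abundant of them, MPO, went from 9795 to 9416 CPM (log2 fold change -0.06, not past the threshold), a level that would hide a small share. Derepression of these genes with less EZH2 may also underlie the rise and was not tested.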
